A study of Homo sapiens with 12 samples.

How the data were processed

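Gene expression was measured by RNA sequencing in 12 libraries of U937, a human pro-monocytic cell line. Per the labels, cells were pretreated with 50 ng/mL interferon gamma and then received a LILRB3 antagonist antibody, a LILRB3 agonist antibody or nonspecific IgG for 72 hours. The labels write the antibody concentration as 5 mg/mL, and that unit is left here as written. Each antibody had its own IgG group, so that the antagonist group and its controls formed set 1 and the agonist group and its controls formed set 2, with 3 libraries per group. Per the labels' protocols, RNA was extracted with Trizol and chloroform and libraries were made with a kit named as a NEBNext Ultra DNA kit. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

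The authors deposited 1 table of whole-number read counts per gene for each set, with no normalization. Per the submitters' processing notes, the tools were HISAT2 and Cufflinks and the genome build was hg38. Tool versions, the program that counted reads, the gene annotation and the use of strand are not given in the sources used here. Without strand, reads of a gene and of an antisense partner cannot be told apart. The column names repeat the group name with no replicate number, so each column was assigned to a group only. The names in set 1 begin with IFN and those in set 2 do not name interferon, although the labels give it for both sets. Column numbers below follow the order in the table and pair nothing. The set 1 table had 28395 rows, of which 570 had no gene symbol. Those rows held a mean of 0.0726% ± 0.0045 (SD, n = 3) of the counts in IgG libraries and 0.102% ± 0.0038 in antagonist libraries, and they stayed out of library sizes and tests.

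The set 2 table listed 904 genes, 902 of them also in the set 1 table. After scaling, the log2 fold changes of listed genes nearest to zero were -0.25 and 0.12, whereas 23.1% of genes in set 1 lay within 0.1 of zero, so the set 2 table was treated as a selected part of a larger one. Its column totals are totals of the listed genes and not library depths. Adjusted p-values for the agonist therefore cover only the listed genes, which were picked on these same libraries, and are not independent evidence of change. TMM and DESeq2 size factors, the scalings used below, assume that most genes are unchanged, which selected genes cannot show. The zero point of agonist fold changes, and of differences between the antibodies, is thus uncertain. Testing each antibody against its IgG with the spread pooled over all 12 libraries was planned for tables that hold the same genes and was not run; only the difference between the antibodies used all 12, over the shared genes.

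Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr at its default settings, libraries were scaled by TMM, and groups were compared within each set by the robust quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. Standard errors (SE) of log2 fold changes were taken from the size of the fold change and the quasi-likelihood F statistic. CPM values of tested genes are TMM-scaled, and CPM values of genes below the filter, and of genes set beside them, are summed counts over summed totals without scaling. The difference between the effects of the antibodies was the interaction of set and treatment over the 902 shared genes, with each set scaled on its own. Levels of LILRB3 and other genes below the filter were compared as summed counts with an exact two-sided test and 95% intervals that cover counting error only.

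The 34 gene lists, the rule for named genes, the tests and the first group of alternatives below were fixed before the data were examined. The lists covered LILR genes, ITIM signalling, interferon, antigen presentation, inflammatory, monocyte, progenitor, cell cycle, death, stress, ribosome, metabolic, lysosome, adhesion and histone genes, mitochondrially encoded genes and markers of T and NK, B, erythroid, and epithelial or fibroblast cells. The 30 lists with at least 5 tested genes were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, and again with an estimated correlation. The planned fry test, which asks whether a list's own members changed without comparing them with other genes, was also run in set 1. It can pass a list that moved no more than other genes, and its p-values are not adjusted over lists. No list was tested against other genes in set 2. There, the direction of the listed members was compared with that of the other listed genes by Fisher's exact test (two-sided, 14 lists), a test chosen after the tables were seen. Named genes were LILRB3, the 10 largest rises and 10 largest falls among genes past 0.05 with fully separated groups and a mean of at least 5 CPM, leaving out uncharacterised and small-RNA symbols, and from each list up to 4 passing members with the smallest p or, where none passed, the 2 with the highest mean. The text names a part of these; LILRA6, H3C4, CD3E, MS4A1, HBB, EPCAM, the genes around LILRB3, and IDO1, CXCL9 and IRF1 in the IgG groups were named after their values were seen.

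The first group of alternatives was DESeq2 size factors in edgeR, the DESeq2 1.42.0 test, no filter beyond a nonzero total, a filter at a mean of 5 CPM, an estimated correlation for the lists and leaving out each library in turn. Added afterwards were totals without a TMM factor and the removal of each library's smooth trend in GC content and transcript length (mgcv 1.9.3, GENCODE 29 transcripts, known for 97.7% of tested genes in set 1 and 98.1% in set 2). Mitochondrially encoded genes carried other symbols in that annotation and were not corrected. Coordinates come from the GRCh38.p14 RefSeq gene table.

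The tests were checked on simulated counts drawn from the real means with 200 changed genes. In the antagonist simulation over 13804 genes, 93.9% of genes changed by a log2 of 1 and 57.6% of those changed by 0.5 were recovered, with 11 false calls. For the agonist simulation over 899 genes these shares were 99.0% and 91.0% with 6 false calls. For the difference over 902 genes, simulated with no antagonist effect, they were 90.0% and 69.0% with 3 false calls. Most simulated genes were unchanged and the changes were balanced up and down, unlike the selected genes of set 2. These figures thus do not show that scaling or error rates hold for the real agonist and difference tests. A planted GC trend gave 3423 false calls among 13817 genes without correction and 7 among 13491 genes with it. A list planted with a rise had an adjusted p of 3.31e-51 with the preset and 0.0021 with an estimated correlation, and none of the other lists was called at either setting. The simulated genes were independent, unlike members of real lists (estimated correlation 0.61 for ribosomal proteins). The check therefore does not show that p-values with the preset are sound for such lists. Library pairs in a group differed by more than sampling noise, with chi-square values per degree of freedom of 1.95 to 26.7, so each library was counted as 1 sample.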

Results

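Transcriptomes of U937 cells, pretreated with interferon gamma per the labels, were compared after 72 hours with a LILRB3 antagonist or agonist antibody. Each antibody was compared with its own nonspecific IgG controls. LILRB3 is an inhibitory receptor of myeloid cells that signals through ITIM motifs, and the labels give interferon gamma as the means to raise its expression. The 12 libraries formed 4 groups of 3. In set 1, total counts were between 17155518 and 18833088 in the IgG libraries and between 17053190 and 17790608 in the antagonist libraries. The table of set 2 was restricted to 904 genes, whose counts summed to between 2764479 and 3522203 per library.

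LILRB3, the receptor bound by both antibodies (chromosome 19, 54216278 to 54223007, GRCh38.p14), was barely counted in set 1. The IgG libraries held 2, 1 and 2 counts and the antagonist libraries 5, 2 and 3. Scaled by the summed library totals, the ratio of antagonist to IgG counts was 2.03 (95% counting interval 0.634 to 7.59, exact two-sided p = 0.206). No difference was thus detectable at this depth. LILRB3 was not among the genes listed for set 2. Of its relatives, LILRA2 had 35.9 ± 5.0 CPM in IgG and 30.7 ± 1.6 CPM in antagonist libraries (SD, n = 3, adjusted p = 0.0958), and the related collagen receptor LAIR1 had 7.68 ± 0.36 and 6.71 ± 0.39 CPM (adjusted p = 0.244). None of the 6 tested genes of the LILR family list passed the test, over all genes or adjusted over the list alone (camera adjusted p = 0.874 for the list; edgeR as above). LILRA2 did pass without IgG library 1 (-0.30), with no filter (-0.23) and after the removal of length and GC trends (-0.20). Reads can be shared between LILRB3 and its near copy LILRA6, with 20.3% of 50-base windows of LILRB3 transcripts also found in LILRA6, and LILRA6 itself had 30 counts over the IgG libraries and 28 over the antagonist libraries.

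With the antagonist antibody, genes of the translation and respiration machinery were lower than with IgG. All 32 tested ribosomal protein genes fell (32 adjusted over the list alone), with a median log2 fold change of -0.44. RPL3 went from 2623 ± 93 to 1936 ± 5 CPM (SD, n = 3 per group), a log2 fold change of -0.44 ± 0.05 (SE), and RPS14 changed by -0.53 ± 0.07. Of 26 nuclear genes of oxidative phosphorylation, 25 fell (25 adjusted over the list alone; median -0.38; adjusted p = 0.301 with an estimated correlation for both lists), among them the complex I subunits NDUFB8 (-0.50 ± 0.07) and NDUFA4 (-0.54 ± 0.08). Of 15 mitochondrially encoded genes, 12 fell and 2 rose (13 and 2 adjusted over the list alone; adjusted p = 0.325 with an estimated correlation). ND2 changed by -0.55 ± 0.06, CYTB by -0.54 ± 0.06 and COX2 by -0.52 ± 0.06, while ND5 rose by 0.59 ± 0.06, from 806 ± 50 to 1212 ± 31 CPM. Ribosomal protein, ferritin and mitochondrial genes have near copies elsewhere in the genome that can share their reads. In the same libraries, 111 of 589 lincRNA and antisense genes were higher with the antagonist and 16 lower, with a median log2 fold change of 0.23 against -0.03 for 12306 protein-coding genes.

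Of the 13778 genes tested, 4978 passed an adjusted p of 0.05, 2147 higher and 2831 lower. Most changes were small: the median absolute log2 fold change among these genes was 0.35, and 100 genes rose and 10 fell by more than 2-fold. The share of higher calls was 43.1% and became 65.4% with library totals in place of TMM scaling. Without antagonist library 1 the count was 3143 and without antagonist library 3 it was 3190. The 3 antagonist and 3 IgG libraries did not overlap for 49.0% of genes, against 10% by chance. By camera, 11 of 30 lists passed an adjusted p of 0.05, all of them lower, and with an estimated correlation 0 passed.

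The set tests of the leading lists gave adjusted p = 3.18e-18 for ribosomal proteins, 6.01e-11 for oxidative phosphorylation and 7.2e-07 for mitochondrially encoded genes. None of these passed with an estimated correlation. Mitochondrially encoded genes took between 4.49% and 4.75% of counts in IgG libraries and between 3.51% and 3.85% in antagonist libraries. For 84 ribosomal protein genes these shares were 6.46% to 7.63% and 5.29% to 5.55%. IgG library 1 stood apart from the other IgG libraries, with chi-square values per degree of freedom of 11.1 and 19.96 against 4.56 between the other two, and without it 31 ribosomal protein genes and 23 oxidative phosphorylation genes fell. Across 13457 genes, which are not independent, log2 fold change had a Spearman correlation of 0.193 with transcript length and 0.279 with GC content. After removal of those trends 31 ribosomal protein genes (median -0.40) and 24 oxidative phosphorylation genes (median -0.26) fell.

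**Figure D1:**
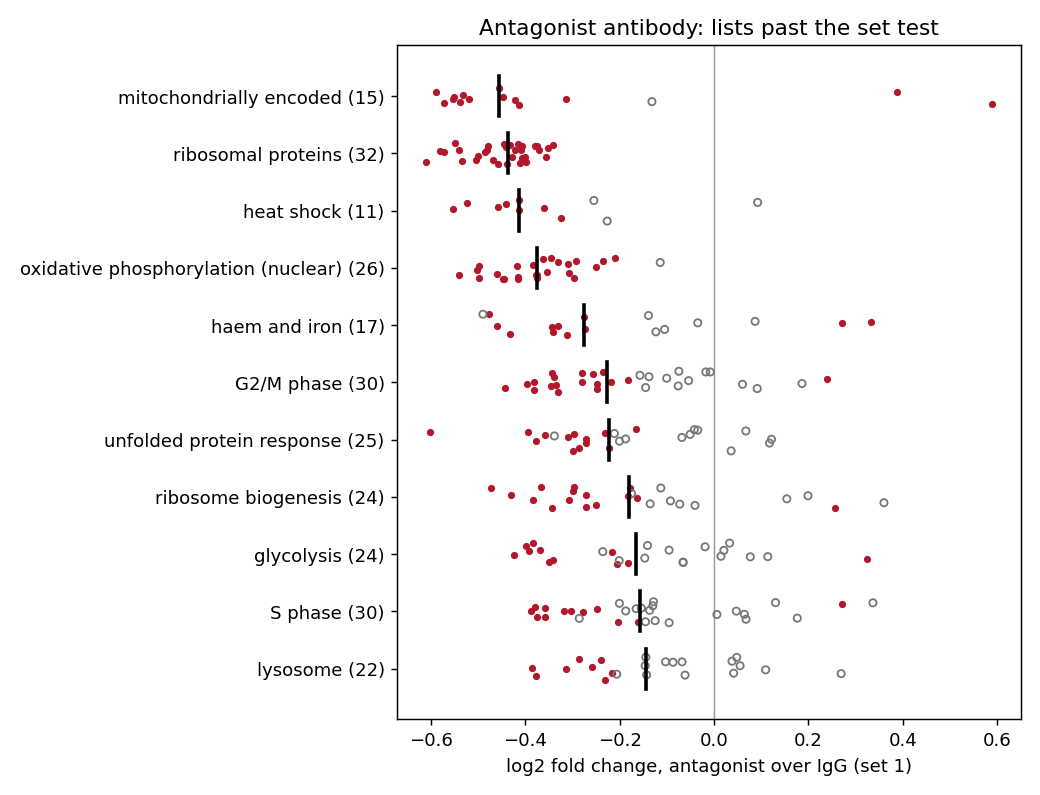
Log2 fold change (antagonist over IgG, set 1; x axis) of each tested gene in the 11 lists past the set test, with the number of tested genes in brackets. Filled points passed an adjusted p of 0.05 and open points did not, and the black bar is the list median, which lay at -0.44 for ribosomal proteins and at -0.14 for the lysosome list.

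Parts of 4 lists of chaperone, stress response and cell cycle genes were also lower with the antagonist. Of 11 heat shock genes 8 fell (10 adjusted over the list alone), including the constitutive chaperones HSPA8 (-0.52 ± 0.06) and HSP90AA1 (-0.46 ± 0.06; list adjusted p = 1.61e-05, adjusted p = 0.222 with an estimated correlation). Of 25 genes of the unfolded protein response 13 fell and 0 rose (16 and 0 adjusted over the list alone), such as its transcription factor XBP1 (-0.38 ± 0.06) and the ER co-chaperone DNAJB9 (-0.60 ± 0.10; list adjusted p = 0.000754, adjusted p = 0.222 with an estimated correlation). Among 30 G2/M genes 17 fell and 1 rose (18 and 1 adjusted over the list alone), with the mitotic cyclins CCNB1 at -0.33 ± 0.06 and CCNB2 at -0.38 ± 0.07. That list had an adjusted p of 0.000754 (adjusted p = 0.341 with an estimated correlation), and 11 members fell with totals in place of TMM. Among 30 S-phase genes 11 fell and 1 rose (13 and 2 adjusted over the list alone), including the replication clamp PCNA (-0.36 ± 0.06) and thymidylate synthase TYMS (-0.36 ± 0.07; list adjusted p = 0.0202, adjusted p = 0.278 with an estimated correlation).

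Part of the genes in 4 further lists were lower with the antagonist. Of 24 MYC-target and ribosome biogenesis genes 14 fell and 1 rose (15 and 3 adjusted over the list alone), with the nucleolar proteins NPM1 at -0.47 ± 0.07 and FBL at -0.43 ± 0.05 (list adjusted p = 0.0046, adjusted p = 0.222 with an estimated correlation). Of 24 glycolysis and hypoxia genes 10 fell and 1 rose (10 and 1 adjusted over the list alone), including GAPDH (-0.37 ± 0.05) and ENO1 (-0.34 ± 0.05; list adjusted p = 0.0155, adjusted p = 0.325 with an estimated correlation). Of 17 haem, iron and oxidative stress genes 9 fell and 2 rose (9 and 2 adjusted over the list alone), and the ferritin light chain FTL went from 5113 ± 294 to 3791 ± 51 CPM (list adjusted p = 0.0155, adjusted p = 0.58 with an estimated correlation). Of 22 lysosome genes 8 fell and 0 rose (9 and 0 adjusted over the list alone; list adjusted p = 0.0428, adjusted p = 0.301 with an estimated correlation). For cholesterol synthesis, 9 of 24 genes fell and 1 rose. The list did not pass camera (adjusted p = 0.0775), while fry put it as lower (unadjusted p = 0.000352).

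Immune lists did not pass camera as sets in the antagonist comparison, while single members changed in both directions. By fry, the interferon gamma list (unadjusted p = 0.0039) and the type I interferon list (0.0437) were lower. The fry p was 0.0581 for the monocyte, 0.0873 for the ITIM signalling and 0.369 for the NF-kB list. Not all members were tested: 25 of 36 genes of the interferon gamma list and 7 of 14 of the MHC class II list were. The interferon gamma targets IDO1 and CXCL9 had 0 and 1 counts over the IgG libraries, while IRF1 had 25.4 CPM by summed counts. A fall of targets at that floor could not be seen here. In the interferon gamma list 2 of 25 genes rose and 7 fell (2 and 9 adjusted over the list alone; list adjusted p = 0.325). The transactivators of antigen presentation genes CIITA (0.66 ± 0.12) and NLRC5 (0.48 ± 0.07) rose, and the proteasome activator subunit PSME1 (-0.48 ± 0.08) fell. In the type I interferon list 1 of 30 genes rose and 6 fell (1 and 6 adjusted over the list alone; list adjusted p = 0.361), with IFI6 at -0.49 ± 0.07. In the monocyte and macrophage list 1 of 29 rose and 7 fell (1 and 4 adjusted over the list alone; list adjusted p = 0.325), with the integrin ITGAX higher (0.42 ± 0.08) and lysozyme LYZ lower (-0.46 ± 0.08). Among 17 genes of ITIM signalling 3 rose and 3 fell (3 and 3 adjusted over the list alone; list adjusted p = 0.936). The ubiquitin ligase CBL (0.41 ± 0.06) rose, while the ITAM adaptors TYROBP (-0.38 ± 0.08) and FCER1G (-0.28 ± 0.07) fell, the latter no longer past the threshold with totals in place of TMM (-0.20). Of 22 NF-kB and inflammatory genes 5 rose and 6 fell (5 and 6 adjusted over the list alone; list adjusted p = 0.908), with the subunit REL at 0.42 ± 0.08 and the chemokine CCL5 at -0.39 ± 0.07. In the NF-kB list the median (-0.04) and the mean (0.03) differed in sign, as they did for the MHC class II list (-0.13 and 0.11), and camera put both as lower; the complement list had a median and mean of 0.01 with a camera direction of lower.

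Further lists also stayed short of the camera threshold. By fry, cholesterol efflux (unadjusted p = 0.00689), adhesion (0.00764) and apoptosis (0.0161) genes were lower, and the other lists below had fry p-values of 0.0514 to 0.855. Of 26 apoptosis and survival genes 2 rose and 7 fell (2 and 6 adjusted over the list alone; list adjusted p = 0.285), with the caspase 8 regulator CFLAR at 0.31 ± 0.06. Of 18 progenitor and leukaemia genes 2 rose and 2 fell (2 and 1 adjusted over the list alone; list adjusted p = 0.874), with the granule protease CTSG going from 3329 ± 38 to 2606 ± 62 CPM. Of 8 tested genes of the anti-inflammatory list 2 rose and 2 fell (2 and 2 adjusted over the list alone; list adjusted p = 0.908), with the angiogenic factor VEGFA at 0.32 ± 0.06. Among 22 adhesion and migration genes 4 rose and 7 fell (5 and 9 adjusted over the list alone; list adjusted p = 0.524), and among 15 MHC class I genes 2 rose and 5 fell, such as the light chain B2M at -0.35 ± 0.06 (2 and 5 adjusted over the list alone; list adjusted p = 0.856). Of 7 MHC class II genes 1 rose and 1 fell (1 and 1 adjusted over the list alone), of 15 complement and phagocytosis genes 1 rose and 3 fell (0 and 3), of 12 checkpoint genes 2 rose and 2 fell (2 and 2) and of 25 immediate early genes 2 rose and 2 fell (1 and 2). The p53 targets had 2 of 19 genes higher and 1 lower (1 and 0 adjusted over the list alone), cholesterol efflux genes 1 of 12 higher and 2 lower (1 and 2) and replication histones 1 of 5 higher and 1 lower (1 and 1), and the adjusted p of these 7 lists was between 0.856 and 0.908. Markers of other cell types were mostly near zero: the T cell receptor gene CD3E had 0 counts in the IgG libraries (95% upper counting limit 0.0693 CPM) and 5 in antagonist library 3, and the B cell gene MS4A1, the globin HBB and the epithelial gene EPCAM had 0 counts in all 6 libraries. Among the few tested markers, CD5 rose from 49 to 170 summed counts (log2 fold change 1.73 ± 0.28) and NKG7 fell (-0.32 ± 0.06). The B lineage factor PAX5 (0.29 ± 0.10), the erythropoietin receptor EPOR (-0.27 ± 0.09) and vimentin VIM (-0.28 ± 0.06) also passed, as 1 of 4, 1 of 3 and 1 of 2 tested markers. EPOR no longer passed in 10 of 12 other settings, among them every scaling or filter alternative except the removal of length and GC trends, and PAX5 was lost without IgG library 2 (0.31), antagonist library 1 (0.24) or antagonist library 2 (0.28).

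The single genes with the largest separated rises under the antagonist included the histone methyltransferase KMT2D (chromosome 12, 49018978 to 49060794), which went from 207 ± 18 to 471 ± 25 CPM (log2 fold change 1.19 ± 0.07, adjusted p = 1.04e-05, higher in 3 of 3 libraries). The basement membrane proteoglycan HSPG2 went from 464 ± 92 to 937 ± 66 CPM. Others were LDC1P (1.49 ± 0.13), the lymphocyte receptor PVRIG (1.28 ± 0.16), ZNF596 (1.18 ± 0.17) and ZBED6 (1.00 ± 0.09), an intron-encoded gene that can share reads with its host. Among the falls were SETMAR (-0.96 ± 0.14), HACD1 (-0.75 ± 0.14), the replication protein RPA3 (-0.74 ± 0.10), the protein kinase A subunit PRKAR2B (-0.77 ± 0.17), the DNA repair factor XRCC4 (-0.74 ± 0.18), the mitochondrial ribosomal protein MRPS24 (-0.73 ± 0.14) and the iron-sulfur assembly factor ISCA1 (-0.71 ± 0.15). MTRNR2L1 (-0.95 ± 0.14) is a near copy of mitochondrial ribosomal RNA, and its counts can come from that RNA.

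With the agonist antibody, listed monocyte and type I interferon genes were higher and listed cell cycle genes lower than with IgG. All 14 listed genes of the monocyte and macrophage list rose, with a median log2 fold change of 0.52. The endotoxin co-receptor CD14 went from 96.2 ± 11.7 to 183 ± 3 CPM of listed counts (SD, n = 3 per group; 0.93 ± 0.11, SE), the protease MMP9 rose by 0.72 ± 0.06 and ITGAX by 0.54 ± 0.06. All 14 listed type I interferon genes rose (median 0.35), led by IFI27 (0.95 ± 0.11) and IFI6 (0.56 ± 0.08), with the virus-tethering protein BST2 at 0.36 ± 0.07. All 16 listed G2/M genes fell (median -0.38), such as the mitotic kinesin KIF2C (-0.35 ± 0.05) and the spindle factor TPX2 (-0.33 ± 0.05). All 7 listed S-phase genes fell (median -0.37), including the helicase subunit MCM6 (-0.37 ± 0.05) and the methylation reader UHRF1 (-0.49 ± 0.09). The full lists hold 41 monocyte, 35 type I interferon, 30 G2/M and 30 S-phase genes, and members not listed could not be judged. The same holds for lists below, with 36 interferon gamma, 27 cholesterol synthesis, 23 lysosome, 32 ribosomal protein and 15 mitochondrially encoded genes in full.

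Of the 904 genes listed for set 2, 903 passed an edgeR adjusted p of 0.05, 503 higher and 400 lower. This count says how the table was made, since the genes were selected on the same libraries, and H3C4 was the exception (adjusted p = 0.0518). Higher calls made up 55.7% and, with DESeq2 size factors, 44.2% of 717, and after removal of length and GC trends 45.7% of 619. For each list, the counts of members adjusted over the list alone equalled those over all listed genes. Against the other listed genes, Fisher's exact test of direction gave adjusted p = 0.00156 for the monocyte list, 0.00156 for type I interferon genes, 2.55e-05 for G2/M genes and 0.00564 for S-phase genes, with 11 of 14 lists past 0.05. This test counts genes as independent, which members of a list are not, so its p-values are too small; among the genes called after removal of length and GC trends 7 lists passed. Agonist library 1 stood apart from the other agonist libraries, with chi-square values per degree of freedom of 25.1 and 26.7 against 3.75.

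**Figure D2:**
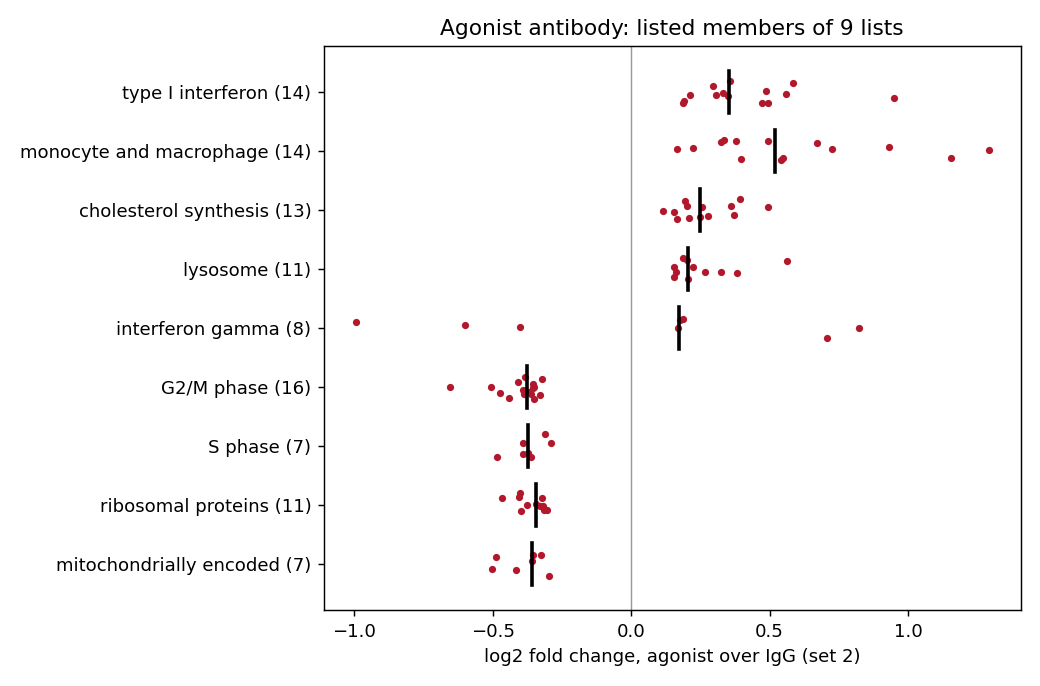
Log2 fold change (agonist over IgG, set 2; x axis) of each listed gene in 9 lists, with the number of listed genes in brackets. Filled points passed an adjusted p of 0.05 and the black bar is the list median; the genes were selected by the authors, and the 16 G2/M genes all lie below zero while the 14 type I interferon genes all lie above it.

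Interferon gamma genes split under the agonist, with 5 of 8 listed members higher and 3 lower (Fisher's exact adjusted p = 1). The lower ones were the chemokines CXCL10 (233 ± 14 to 154 ± 10 CPM, -0.60 ± 0.09) and CXCL11 (-0.99 ± 0.18) and the tryptophanyl-tRNA synthetase WARS1 (-0.40 ± 0.06), and the complement inhibitor SERPING1 rose by 0.82 ± 0.18. In the anti-inflammatory list 4 of 5 genes rose and 1 fell (adjusted p = 0.42). The haemoglobin scavenger receptor CD163 rose by 0.80 ± 0.11, the fatty acid receptor CD36 by 0.58 ± 0.09 and the folate receptor FOLR2 by 1.33 ± 0.41, while the interleukin 1 receptor antagonist IL1RN fell (-0.38 ± 0.09). The cytokine IL10 (chromosome 1, 206767602 to 206772494) had 1 count over the 3 IgG libraries and 69 over the 3 agonist libraries. Scaled by the totals of listed counts, which are not library depths, the ratio was 63.6 with a 95% counting interval of 11.03 to 2546. The agonist libraries held 16, 16 and 37 counts and the IgG libraries 1, 0 and 0, so the size of the ratio rests on 1 control count.

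Cholesterol and lysosome genes were higher with the agonist, by small amounts that depended on scaling. Which scaling is nearer the truth cannot be told from selected genes. All 13 listed cholesterol synthesis genes rose (median 0.25; Fisher's exact adjusted p = 0.00243), including HMG-CoA synthase HMGCS1 (0.49 ± 0.06), INSIG1 (0.37 ± 0.05) and MSMO1 (0.39 ± 0.06). All 11 listed lysosome genes rose (median 0.20; adjusted p = 0.00387), including the cathepsins CTSB (0.32 ± 0.05) and CTSD (0.23 ± 0.05). With DESeq2 size factors 7 and 5 of these passed as higher. After removal of trends in GC content and length 8 and 4 passed as higher and 1 lysosome gene passed as lower (Fisher's exact adjusted p = 0.201 for the lysosome list among the genes called then), with CTSB at 0.036 and CTSD at -0.042. Log2 fold change had a Spearman correlation of 0.351 with GC content and -0.28 with length across 887 listed genes.

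Listed ribosomal protein and mitochondrially encoded genes fell with the agonist. All 11 listed ribosomal protein genes were lower (median -0.34; Fisher's exact adjusted p = 0.000824), with RPL3 at -0.41 ± 0.06 and RPS6 at -0.34 ± 0.05, and all 7 listed mitochondrially encoded genes were lower (median -0.36; adjusted p = 0.00564), with ND4L at -0.49 ± 0.06 and ND1 at -0.36 ± 0.05. The growth-promoting transcription factor MYC fell by 0.58 ± 0.07 and the haematopoietic factor RUNX1 by 0.47 ± 0.08. Of 10 listed immediate early genes 9 rose and MYC fell (adjusted p = 0.0574), with the phosphatase DUSP1 at 0.94 ± 0.19 and the mRNA-decay factor ZFP36 at 0.46 ± 0.08. All 7 listed adhesion genes (adjusted p = 0.0306, and 0.131 after the trend removal), 6 complement and phagocytosis genes (adjusted p = 0.0471) and 6 checkpoint ligands and receptors (adjusted p = 0.0471) rose, among the last VSIR (0.31 ± 0.07). The direction test of complement genes no longer passed without IgG library 2 (adjusted p = 0.0762), without agonist library 3 (0.0773) or with totals in place of TMM (0.0803), and that of checkpoint genes without agonist library 3 (0.0773), while that of immediate early genes passed with DESeq2 size factors (0.0232) and with any 1 library left out except agonist library 1. Fewer than 5 checkpoint genes were called with DESeq2 size factors, the DESeq2 test or the trend removal, so their direction was not tested there. The same held for complement genes with the DESeq2 test. The 2 listed genes of ITIM signalling rose, TYROBP by 0.54 ± 0.09 and FCER1G by 0.30 ± 0.07. Lists with fewer than 5 listed genes were not tested for direction: 3 genes each of oxidative phosphorylation, cholesterol efflux, haem and iron, and histones rose, as did 2 of MHC class I and 1 each of MHC class II, NF-kB, glycolysis, and T and NK cells. Lower were 2 each of progenitor, ribosome biogenesis, unfolded protein response and heat shock genes. The ferritin heavy chain FTH1 rose by 0.37 ± 0.05. B2M was higher by 0.19 ± 0.05 and did not pass with DESeq2 size factors (0.09). The lymphoid granule gene NKG7, the 1 listed marker of T and NK cells, was higher by 0.22 ± 0.07 and did not pass with DESeq2 size factors (0.13) or after the trend removal (-0.12).

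**Figure D3:**
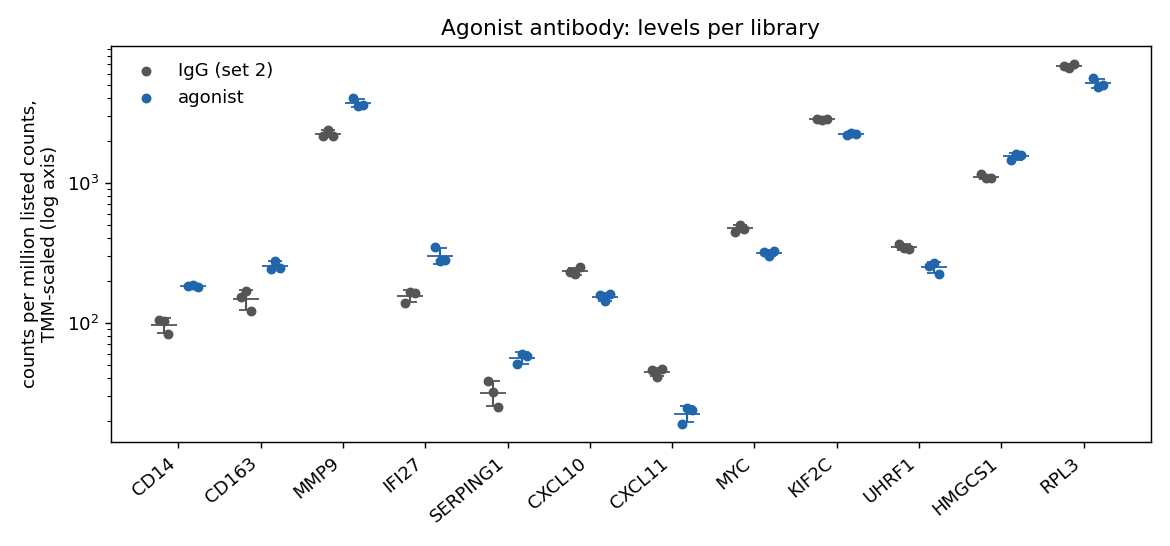
TMM-scaled CPM of listed counts (log y axis) of 12 named genes in each IgG (grey) and agonist (blue) library of set 2; the points are libraries, and the horizontal mark and bars are the mean and SD (n = 3). CD14 lies at 96.2 CPM in IgG and 183 CPM in agonist libraries, and CXCL11 at 44.6 and 22.4 CPM.

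The largest separated rises with the agonist included the acid phosphatase ACP5 (1.91 ± 0.49), the surface glycoprotein CD52 (9.36 ± 7.64 to 34.6 ± 4.8 CPM), the protease inhibitor A2M (1.47 ± 0.24) and the calcium-binding protein S100A12 (1.29 ± 0.30). The largest falls included RNF112 (-2.09 ± 0.44), the integrin ITGB4 (-1.86 ± 0.46), the orphan receptor GPR176 (-1.80 ± 0.36) and CD247 (45.9 ± 3.2 to 21.3 ± 2.3 CPM), which encodes the T cell receptor zeta chain.

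The design also asks whether blocking and engaging the receptor changed genes differently. Several named genes moved in opposite directions. FTH1 fell with the antagonist (-0.28) and rose with the agonist (0.37), a difference of antagonist minus agonist effect of -0.65 ± 0.08 (SE, adjusted p = 1.49e-05), and for FTL the difference was -0.64 ± 0.08. TYROBP differed by -0.92 ± 0.13, FCER1G by -0.58 ± 0.10, IFI6 by -1.05 ± 0.12 and BST2 by -0.72 ± 0.11. RUNX1 rose with the antagonist (0.25) and fell with the agonist (-0.47), a difference of 0.72 ± 0.11, and the mitochondrial gene ND5 differed by 1.01 ± 0.09. By contrast, RPL3 fell with both, and its effects did not differ detectably (-0.03 ± 0.08, adjusted p = 0.733).

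Of the 902 shared genes, 510 passed an adjusted p of 0.05 in the test of the difference, 242 with a higher and 268 with a lower antagonist effect. Since these genes were selected on the agonist libraries, a gene that the antagonist left unchanged could pass by that selection alone. Among 867 genes tested in both tables, 401 passed in both comparisons. Of these 229 went the same way, 101 up and 128 down, where independent calls would give 85.1 and 111, and 172 went opposite ways. For 118 genes the agonist effect was up and the antagonist effect down (135 for independent calls) and for 54 the reverse (69.9). All 172 also passed the test of the difference. This adds no support, since genes past 0.05 in both comparisons with opposite signs were nearly bound to pass it. Across these genes, which are not independent and were selected on the agonist libraries, the effects had a Pearson correlation of 0.0375 and a Spearman correlation of 0.0388. As sets in the antagonist comparison, genes lower with the agonist were lower (54 of 391 up and 128 down, camera p = 0.019; p = 0.14 with an estimated correlation), and for genes higher with the agonist camera gave p = 0.887 (101 of 476 up and 118 down). The antibodies were compared through separate IgG groups, so a difference between the sets other than the antibody is part of each value.

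**Figure D4:**
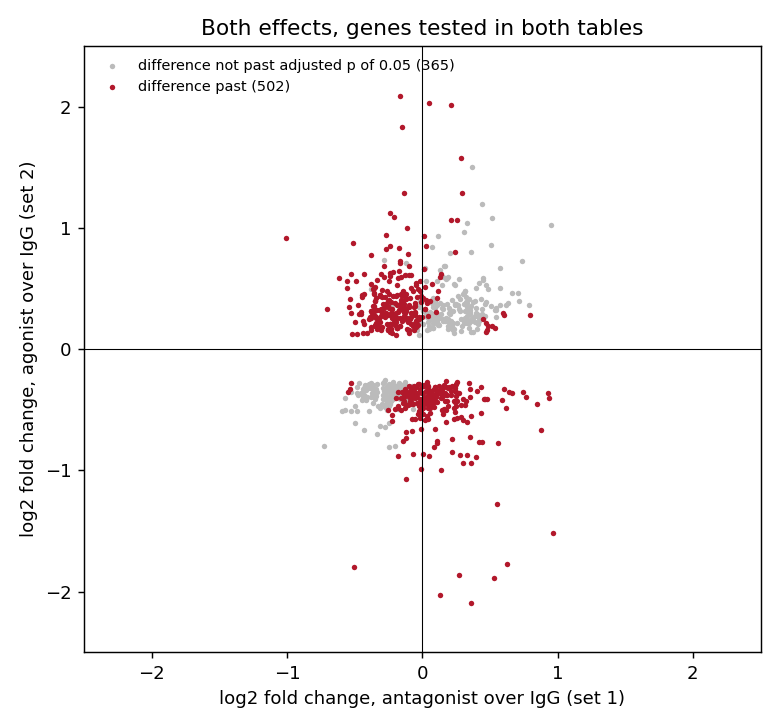
Log2 fold change of the antagonist over IgG in set 1 (x axis) against that of the agonist over IgG in set 2 (y axis) for 867 genes tested in both tables. Red points (502) passed the test of the difference and grey points (365) did not; 4 genes lie outside the axes, and the empty band around zero on the y axis reflects the selection of the listed genes.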

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

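The tests of length and GC trends, of reads shared with paralogs and of the genes around LILRB3 were chosen only after the results they bear on were seen.

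A difference between the effects of the antibodies was the reason for a closer look at most of these results. The 902 shared genes were selected on the agonist libraries, so a gene that the antagonist left unchanged could be called by that selection alone. The test of the difference called 510 of these 902 genes. Among named genes it put the antagonist effect below the agonist effect for IL10 (-5.90, with 1 control count in set 2 and 4 counts per group in set 1), CD14 (-1.72, with 22 and 13 counts in set 1), IFI6 (-1.05), TYROBP (-0.92), MMP9 (-0.89), BST2 (-0.72), FCER1G (-0.58), B2M (-0.54), CTSB (-0.47) and VSIR (-0.44). The antagonist effect was also the lower one for FTH1 (-0.65), FTL (-0.64), NKG7 (-0.55), the cholesterol genes MSMO1 (-0.65), HMGCS1 (-0.52) and INSIG1 (-0.51), DUSP1 (-1.21), HSPA8 (-0.25), CYTB (-0.21) and ND2 (-0.20). It lay above the agonist effect for RNF112 (2.46), CD247 (2.41), ITGB4 (2.14), GPR176 (1.30), ND5 (1.01), RUNX1 (0.72), MYC (0.52), UHRF1 (0.49), ND1 (0.23), WARS1 (0.21) and KIF2C (0.17). RNF112, CD247, ITGB4 and GPR176 were named for their large agonist falls, so their values follow in part from how they were picked. With DESeq2 size factors or totals in place of TMM, HSPA8, CYTB and ND2 no longer passed.

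Of 100 splits drawn within the sets, 3 gave as many genes for the difference, the real one included, with a highest other count of 544. All 3 kept the real agonist groups, which 7 of the drawn splits did, and no split that kept neither real grouping called a gene. The listed genes were selected on the real agonist groups, so these splits do not bear on chance. For the antagonist alone, 1 of the 10 splits of its 6 libraries gave as many as 4978 genes, the real one, and the highest other count was 0. For the agonist 1 of 10 did, with 903 genes and 0 in the highest other split. With 10 splits a share under 0.05 is out of reach.

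A signal also appeared in data outside the comparisons: rows without a gene symbol held 0.102% of counts in antagonist libraries and 0.0726% in IgG libraries of set 1 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows).

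The fall of ribosomal, respiratory and mitochondrial genes with the antagonist was weighed against technical explanations. Removal of length and GC trends left the ribosomal list at a median of -0.40 (MAD 0.0954) from -0.44, which argues against those trends as the whole cause for nuclear genes (mitochondrially encoded genes were not corrected), and 31 members fell without IgG library 1, which argues against that library. More unspliced or nuclear RNA in the antagonist libraries remains a possible explanation: after the correction, 589 lincRNA and antisense genes had a median of 0.28, at percentile 100 of 10000 expression-matched draws of coding genes (median 0.08). That account leaves the rise of ND5 beside the fall of ND2 without an explanation. An effect of the antibody is also open, and neither is separated from the other by these libraries.

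The near absence of LILRB3 counts in set 1 has several candidate explanations. LILRB3 and LILRA6 together reached 0.69 CPM and 72.8% of 50-base windows of LILRB3 were unique among GENCODE 29 transcripts. This argues against reads lost to that paralog as the main cause. Other copies of the sequence in the genome build were not searched. Counts may have been lost over the surrounding stretch: 5 of 5 neighbouring genes from families with a median of at least 1 CPM (NDUFA3, TSEN34, PRPF31, CNOT3 and RPS9) ranked low in their families, RPS9 at position 8 from the lowest beside 29 others and the rest at positions 1 to 3, with NDUFA3 at 1.03 CPM against a family median of 51.4. Against an even loss, LILRA2 in the same cluster had 34.7 CPM in IgG libraries, and MBOAT7, left out because its family has a median of 0.168 CPM, had 19.03 CPM, the highest of that family. Low expression of LILRB3 stays open as well, as no untreated library was analysed here. The labels give interferon gamma as the means to raise LILRB3. In the IgG libraries of set 1 the chemokines CXCL9, CXCL10 and CXCL11 together had 0.203 CPM, while IRF1 had 25.4 CPM. A link between these levels and that of LILRB3 was not tested.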

How the results depend on the processing

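The length and GC correction, totals without a TMM factor, and list counts under size factors or with a library left out were chosen after the data were seen. No paired analysis was possible because the columns carry no replicate numbers. Testing each antibody against its IgG with the spread pooled over all 12 libraries was planned and not run, since the tables hold different genes (the difference was fitted over the 902 shared genes); a replicate block needs numbers, and a pseudocount does not apply to counts. The antagonist count of 4978 ranged from 4309 to 5519 over other settings and from 3143 to 5075 when 1 library was left out, the lowest without antagonist library 1 and 3190 without antagonist library 3. Of these, 1374 and 1419 were higher and 1769 and 1771 lower, against 2147 and 2831, and with totals in place of TMM 1597 were lower. Of the 4978 genes, 3104 kept their call and direction without antagonist library 1 and 3901 after the length and GC correction, which turned the sign of 50. The agonist count of 903 ranged from 619 to 903 and, with 1 library left out, from 846 to 885, and the correction turned the sign of 63 of these genes. The 503 higher agonist genes became 317 with DESeq2 size factors, 308 with the DESeq2 test and 283 after the correction, since the first 2 scalings shift the median by -0.09. The difference count of 510 ranged from 461 to 536 and from 463 to 547, and the 229 genes called in the same direction from 160 to 246 and from 155 to 234. The count of 11 lists called by camera was 0 with an estimated correlation, 10 with DESeq2 size factors and 9 to 11 with a library left out; the correction could not be applied to the mitochondrially encoded list, and the 10 others all passed after it. The 11 agonist lists past the direction test, recomputed after the data were seen among the genes called in each setting, were 10 to 12 with a library left out, 10 to 11 with other scalings, filters or the DESeq2 test, and 7 after the length and GC correction, which also leaves out the mitochondrially encoded list and leaves fewer called genes.

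Within lists, 31 to 32 ribosomal protein, 21 to 25 oxidative phosphorylation and 12 mitochondrially encoded genes fell with the antagonist in every setting run for them. With the agonist, 11 to 14 monocyte and 13 to 14 type I interferon genes passed with a library left out, in a table selected on these libraries. With DESeq2 size factors, the DESeq2 test and the length and GC correction these counts were 12, 12 and 11 for monocyte genes and 11, 10 and 11 for type I interferon genes. The G2/M count with the antagonist was 11 with totals in place of TMM. With the agonist, 7 cholesterol and 5 lysosome genes passed as higher with DESeq2 size factors and with the DESeq2 test, and 8 and 4 after the length and GC correction, where 1 lysosome gene passed as lower. The cause was not tested. That correction turned CTSD to -0.042 and NKG7 to -0.12, neither past the threshold. Over 1400 values of named genes under other settings, 1370 kept their direction and side of the threshold, 25 were no longer past it, 3, all LILRA2, newly passed and 2 turned. LILRB3 stayed between 0.112 and 0.159 CPM. Its 5 and 10 counts per group limit any statement on it.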

Other observations

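The tests of scaling, of listed genes within 300000 bases and of interferon chemokine levels were chosen only after the result was seen.

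The IgG libraries of the 2 sets, which carry the same sample labels apart from the set, differed widely over the 902 shared genes. Their column names differ, with IFN named only in set 1. Within a set, correlations of log2 levels between IgG libraries were at least 0.993, and between sets they were 0.786 to 0.809. Levels are given as CPM of the shared genes, with each table normalized separately, so the values stand side by side and were not tested. The chemokine CXCL10 had 0 counts in the IgG libraries of set 1 and 2165 in those of set 2, at least 205-fold higher against a floor of 3 counts per library, and CD163 was at least 129-fold higher. Monocyte genes were higher in set 2 for 13 of 14 listed genes (median log2 ratio 3.42), with CD14 at 2.80 ± 0.64 and 96.7 ± 11.5 CPM and MMP9 at 12.4 ± 3.4 and 2259 ± 139 CPM (SD, n = 3). Type I interferon genes were higher for 14 of 14 (median 2.73), with IFI27 111-fold higher, and interferon gamma genes for 7 of 8 (median 3.36). G2/M genes were higher for 16 of 16 (median 1.26), and ribosomal protein genes for 0 of 11 (median -1.33). By summed counts, in set 1 the interferon gamma targets IDO1 and CXCL9 had 0 and 1 counts over the IgG libraries, while IRF1 had 25.4 CPM.

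Technical accounts of this gap between the IgG groups were weighed. The medians of the type I interferon and ribosomal protein lists lay 4.06 apart on the log2 scale in opposite directions, which argues against depth or scaling, and the interferon list lay at percentile 100 of 10000 random lists of listed genes matched on level, which argues against selection of the listed genes. Counts lost over whole regions of the set 1 table were tested on the 4 nearest coding genes, whose levels lay at percentile 0.01 of random sets, below the bound of 2.5 set in advance for such a loss, but 37.9% of those neighbours were members of the same clusters or lists, and reading the test as open for that reason was decided after its result; 27 other listed genes within 300000 bases, near 19 of the 36 listed interferon and monocyte genes, had a median log2 ratio of 0.83 (MAD 1.43), between 0.017 for the remaining genes and 3.01 (MAD 2.60) for those 36, so a loss over regions stays open as part or all of the gap. A weak or absent interferon response in set 1 may account for part of the gap: CXCL9, CXCL10 and CXCL11 together had 0.203 CPM in its IgG libraries, but without an untreated library this cannot be told apart from a difference in the cells themselves. No biological explanation for a difference between the sets is given by the sample labels. Whether the absence of IFN from the set 2 column names reflects a difference in treatment cannot be told. The difference between antagonist and agonist effects was measured on these unlike backgrounds.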
